A study of Homo sapiens with 36 samples.

How the data were processed

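RNA was sequenced from EA.hy926 cells, a human endothelial hybrid line grown as a monolayer, after exposure to perfluorooctanoic acid (PFOA), a persistent perfluoroalkyl acid. There were 36 libraries in 12 groups of 3 biological replicates. The short exposure lasted 48 h at 1, 10 or 100 µM, and the long exposures lasted 6 or 12 weeks at 1, 10 or 100 nM. Each exposure had its own vehicle control with 0.05% DMSO. Per the labels' protocols, RNA was extracted with TRIzol, all RNA integrity numbers lay above 9, and mRNA libraries were read as 150 bp pairs on a DNBSEQ instrument. Cells of the long exposures were collected while being passaged, and those of the short exposure were lysed in the dish.

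The deposited values are a signal per gene, namely read counts that the authors divided by a size factor for each library. Per the submitters' processing notes, HISAT, Bowtie2 and DESeq2 were used with the build GRCh38.p14, without versions. The counting tool and the use of strand are not given in the sources used here. Each exposure time has 1 table of 47137 genes, of which 18048 hold values. Of the entries at 6 weeks, 1 names no gene and holds no value. Within each library the values are whole multiples of a single step, so whole reads were recovered, with 100% of values within 0.01 of a whole read. For control replicate 3 at 6 weeks the step was 1.01, near 1. Its values lay within 4.26e-05 of whole multiples of that step, and 1.35% of those above 0 within 0.01 of a whole number. The recovered size factors lay closer to factors computed over all 36 libraries (SD of the log2 ratio 0.00384 to 0.00460) than over 1 table (0.00755 to 0.0106). Tests between groups were kept within a table, and the tables were joined only for differences of differences, where a scale factor cancels.

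The main test was limma 3.58.1 in R 4.3.3 with an intensity-dependent prior on log2(signal + 1), fitted to the 12 libraries of a table with 1 mean per group. Genes with a mean of at least 10 were tested, which left 12233 genes at 48 h, 12201 at 6 weeks and 12304 at 12 weeks. Fold changes are on the log2(signal + 1) scale, which understates the change of low genes. All tests were two-sided, and a gene passed with a Benjamini-Hochberg adjusted p under 0.05. Each dose was compared with its own control. A dose trend was the slope per step of a line through the 4 group means. The difference between 12 and 6 weeks was tested on 24 libraries and 12037 genes. With 3 libraries against 3, there are 10 splits of a pair of groups, and an exact permutation test of a single value could not go below p = 0.1.

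Gene lists were tested with camera, with a preset correlation of 0.01 between genes, then with an estimated correlation and with fry. Adjustment was over the lists within a comparison. The 26 lists covered PPAR targets and fatty acid oxidation, cholesterol synthesis and uptake, fatty acid synthesis, NRF2 oxidative stress, ATF4 amino acid stress, endoplasmic reticulum chaperones, heat shock chaperones, metallothioneins, endothelial identity, endothelial inflammation and NF-kB, coagulation and fibrinolysis, interferon response, mitosis, DNA replication, p53 targets, the AHR, CAR and PXR xenobiotic response, hypoxia and glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded genes, extracellular matrix, mesenchymal transition, epithelial markers, leukocyte markers, immediate early genes, ribosomal proteins and replication-dependent histones. Metallothioneins had 4 tested genes and leukocyte markers 1, below the minimum of 5, so both are given as gene values. The tests, the lists and a set of 26 single genes, of which 22 passed the filter in each table, were fixed before the data were examined.

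Genes were named by a rule fixed at the same time. Passing genes with a mean of at least 50, an official symbol and no overlap between treated and control libraries came first, up to 12 in each direction. Where fewer than 5 passed, the 5 with the smallest unadjusted p that met the other conditions could be named as not passing. Members of the lists and the 26 single genes could be named in any comparison. Genes that share reads with a near copy or an overlapping gene, such as readthrough genes, were left unnamed because the counting could split their reads. Results of some genes that the rule allows are not reported here. Gene positions are from the RefSeq annotation of GRCh38.p14. Transcript GC content and length are those of the longest transcript in GENCODE release 29, known for 98.8% of the tested genes at each time.

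Each result was recomputed with pseudocounts of 0.1 and 10, no filter and a mean of at least 50, quantile normalization, library quality weights, a replicate block, a minimum fold of 1.5, only the groups compared, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Further settings were chosen after seeing the data. They were a correction for GC content and length, alone or with the block or the weights, the first 1 to 4 principal components as covariates, a gene-by-gene weight algorithm, and leaving out the 4 libraries with a GC gap above 1.8. The GC gap is a library's median log2 deviation of the genes in the upper quartile of GC content minus that of the lower quartile. List tests with left-out libraries and on the differences between times, and agreement under other settings, were also chosen then.

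The tests were checked on simulated counts with the real means and depths and with 200 genes changed by known folds, for the highest dose at each time. Without added structure, limma recovered 37.3% of 1.5-fold, 91.0% of 2-fold and 97.0% of 4-fold changes in a simulation of the 48 h 100 µM comparison over 12233 genes. When the first principal component of the real libraries was added, it recovered 0%, 2.99% and 40.9%, with 0 false calls. For the 100 nM comparisons the corresponding shares with that component were 0%, 4.48% and 54.5% over 12201 genes at 6 weeks and 0%, 0% and 39.4% over 12304 genes at 12 weeks. With the component as a covariate in the same 3 comparisons they were 31.3%, 88.1% and 95.5% at 48 h, 10.4%, 55.2% and 92.4% at 6 weeks, and 5.97%, 38.8% and 95.5% at 12 weeks, but the covariate recovered 0% of each where no component had been added. Library quality weights from the gene-by-gene algorithm gave 4664, 3367 and 32 false calls with that component in these comparisons at 48 h, 6 weeks and 12 weeks. The default weight algorithm was not simulated. Under the same component, between 1 and 4 of 24 unchanged lists were called in each of 5 simulations with the preset correlation and 0 with the estimated one. A list of 20 genes changed 1.5-fold was then called in 5, 4 and 5 of 5 simulations at 48 h, 6 weeks and 12 weeks with the preset correlation and in 4, 0 and 5 with the estimated one. With the component as a covariate it was called in 5 of 5 with either, and 0 unchanged lists were. Figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.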

Results

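Messenger RNA was sequenced in EA.hy926 cells after PFOA exposure at micromolar doses for 48 h or nanomolar doses for 6 or 12 weeks. The 36 libraries formed 12 groups of 3 biological replicates, with a vehicle control at each time. Recovered reads per library ran from 18444181 to 19466331 at 48 h, 18393069 to 19407559 at 6 weeks and 17815292 to 19077902 at 12 weeks. Between 14192 and 15050 genes had a read in a library. Each dose was compared with the vehicle control of its time. Values are normalised read counts given as mean ± SD (n = 3), and fold changes are on the log2 scale with their standard error.

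Ribosomal protein and mitochondrially encoded transcripts, which are among the most abundant in these cells, took different shares of the reads in libraries of the same group. The mitochondrial share ran from 5.35% to 11.6% at 48 h, from 5.58% to 11.4% at 6 weeks and from 5.51% to 10.3% at 12 weeks. The ribosomal protein share ran from 9.34% to 19.2%, from 8.73% to 17.9% and from 10.2% to 20.6% in the same order. The first principal component held 78.0%, 83.8% and 69.2% of the variance at 48 h, 6 weeks and 12 weeks. Across genes, which are not independent replicates, its loading correlated with GC content (r = 0.642, 0.722 and 0.705) and with log transcript length (r = -0.407, -0.394 and -0.407). Over the 36 libraries the library score rose with the ribosomal share (r = 0.893, rho = 0.925), and r was 0.881 without the 2 libraries farthest from the median. For the mitochondrial share r was 0.836 and rho 0.860, with r = 0.843 without such libraries, and for reads per library r was 0.399 and rho 0.549, with r = 0.722. Permutation p was 1e-05 for r and rho of both shares, the smallest that 100000 permutations can give, and 0.0159 for r and 0.0006 for rho of reads. Over these 3 relations the adjusted p was 1.5e-05 for both shares and 0.0159 for r of reads. At 6 weeks all libraries at 10 and 100 nM had ribosomal shares of 8.73% to 15.1%, below all 3 control libraries at 16.0% to 17.9%.

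After 48 h at 100 µM, ASNS, which encodes asparagine synthetase, had a count of 2456 ± 236 against 1314 ± 193 in controls, a log2 fold change of 0.91 ± 0.24. WDR89 was at 310.1 ± 35.2 against 186 ± 5.20, and FHIP2A at 411 ± 49.7 against 241 ± 3.73. PLCB4, a phospholipase C, and ST6GALNAC3, a sialyltransferase, had fold changes of 0.89 ± 0.26 and 1.05 ± 0.31. On the lower side, JUND, a subunit of the AP-1 transcription factor, was at 662 ± 35.3 against 1253 ± 319, and CLEC14A, an endothelial surface lectin, at 722 ± 271 against 1323 ± 288. AKNA and FAM43A had fold changes of -0.80 ± 0.23 and -0.64 ± 0.20. None of these passed, since limma called 0 of 12233 genes (smallest adjusted p = 0.993, 244 at an unadjusted p under 0.05), edgeR 0 and DESeq2 0. The groups did not overlap for 1318 genes, where chance gives 10% on average. ASNS lies on chromosome 7 from 97851677 to 97928441, and JUND on chromosome 19 from 18279694 to 18281622, in GRCh38.p14.

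Of the 26 tested genes of the ATF4 response, which supplies amino acids under stress, 19 were higher and 7 lower, with a median of 0.22 (camera adjusted p = 0.0113, and adjusted p = 0.175 with an estimated correlation). Besides ASNS, its members CHAC1, a glutathione-degrading enzyme, and CARS1, a cysteinyl-tRNA synthetase, had fold changes of 1.70 ± 0.72 and 0.52 ± 0.23, and PHGDH, the entry enzyme of serine synthesis, 0.82 ± 0.51. DNA replication genes were lower in 19 of 24 cases, with a median of -0.33 (adjusted p = 0.000165, and 0.175 as the adjusted p with an estimated correlation), including the helicase subunit MCM3 at -0.68 ± 0.28 and the licensing factor CDC6 at -0.51 ± 0.30. Immediate early genes had a median of -0.41, with 12 of 15 lower (adjusted p = 0.000165, and adjusted p = 0.175 with an estimated correlation), among them FOS at -1.44 ± 0.70 and the flow-responsive KLF2 at -0.78 ± 0.29. Fatty acid synthesis had a median of -0.18, with 11 of 14 lower (adjusted p = 0.0198, and adjusted p = 0.502 with an estimated correlation), and its members FASN, the fatty acid synthase, and SREBF1, its transcriptional activator, had fold changes of -0.68 ± 0.25 and -0.64 ± 0.21. Endoplasmic reticulum chaperones were lower in 15 of 17 cases (median -0.29, adjusted p = 0.00402, and adjusted p = 0.502 with an estimated correlation). Ribosomal proteins (median 0.46, adjusted p = 4.41e-05), the nuclear-encoded respiratory chain (0.38, adjusted p = 0.00167) and mitochondrially encoded genes (0.57, adjusted p = 0.0319) were higher, each with an adjusted p of 0.613 with an estimated correlation. The ribosomal share was 12.8% to 18.4% at 100 µM and 11.2% to 15.8% in controls. In these lists 0 genes passed adjusted over the list alone, and over all genes 0. With the first component as a covariate 6 ATF4 and 2 ribosomal protein genes passed as higher adjusted over the list alone and 4 DNA replication, 3 immediate early and 2 fatty acid synthesis genes as lower, and with 3 components the respiratory chain and mitochondrially encoded genes turned to -0.082 and -0.055 (adjusted p = 0.0831 and 0.686). Without replicate 3 at 100 µM the adjusted p of the ATF4 list was 0.0662. Calls also ended for fatty acid synthesis without that library, control replicate 2 or replicate 1 at 100 µM (0.0662 to 0.122), mitochondrially encoded genes without control replicates 1 or 2 or replicates 1 or 2 at 100 µM (0.0952 to 0.208) and the respiratory chain without replicate 1 at 100 µM (0.146).

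At 10 µM the same direction was seen for WDR89 (0.74 ± 0.20), FHIP2A (0.81 ± 0.22) and ASNS (0.53 ± 0.24). ZBTB33, a methyl-CpG-binding repressor, was at 721 ± 47.9 against 394 ± 37.3, and KBTBD6 and CDCA2 had fold changes of 0.94 ± 0.26 and 0.78 ± 0.23. LPCAT4, a lysophospholipid acyltransferase, was at 1104 ± 491 against 2430 ± 502, and HES1, a Notch target, at 177 ± 70.4 against 347.5 ± 30.5. FRS3, NAB2 and MAP2K3 had fold changes of -1.12 ± 0.31, -0.93 ± 0.27 and -0.79 ± 0.22. Immediate early genes had a median of -0.55, with 13 of 15 lower (camera adjusted p = 0.00037, and adjusted p = 0.32 with an estimated correlation). Endoplasmic reticulum chaperones had a median of -0.31 (adjusted p = 0.00537), the respiratory chain 0.35 (adjusted p = 0.00537) and mitochondrially encoded genes 0.60 (adjusted p = 0.0131), each with an adjusted p of 0.733 with an estimated correlation. Ribosomal proteins had a median of 0.32 (adjusted p = 0.00445, and adjusted p = 0.797 with an estimated correlation), which was -0.08 after quantile normalization and -0.16 without replicate 3 at 10 µM, and without that library the adjusted p was 0.0998 for the immediate early list and 0.837 for endoplasmic reticulum chaperones, the respiratory chain and mitochondrially encoded genes. Calls of ribosomal proteins, the respiratory chain and mitochondrially encoded genes also ended without control replicate 2 or replicate 1 at 10 µM (0.0894 to 0.35), and that of mitochondrially encoded genes without control replicate 1 (0.0504). With 4 components as covariates the respiratory chain turned to -0.10 (adjusted p = 0.0194). The ribosomal share at 10 µM ran from 9.34% to 19.2%. No list had a gene passing adjusted over the list alone (0, and 20 genes with the first component as a covariate), and over all genes limma called 0 (345 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1.

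At 1 µM, ZNF484 had the smallest p among the genes that could be named, with a count of 57.9 ± 11.9 against 36.4 ± 5.95, a fold change of 0.65 ± 0.27 that did not pass. No list passed, and limma called 0 genes (6 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1. Across the 4 groups the slopes per dose step were 0.31 ± 0.07 for ASNS, 0.27 ± 0.06 for WDR89, 0.61 ± 0.23 for CHAC1, -0.32 ± 0.08 for JUND and -0.28 ± 0.09 for KLF2. Of all genes 0 passed for the trend (smallest adjusted p = 0.808, 520 at an unadjusted p under 0.05, and 0 by edgeR and 0 by DESeq2), and adjusted over the list alone ASNS was the 1 gene of the ATF4 list that passed, against 0 with the replicate block and 6 with the first component as a covariate. The 8 lists called at 100 µM were also called for the trend, in the same directions. Immediate early genes had a median slope of -0.18 (adjusted p = 0.000192, and adjusted p = 0.323 with an estimated correlation), DNA replication -0.11 (adjusted p = 0.000621, and adjusted p = 0.35 with an estimated correlation) and ATF4 genes 0.07 (adjusted p = 0.0475, and adjusted p = 0.408 with an estimated correlation), and the other 5 each had an adjusted p of 0.562 with an estimated correlation. The ATF4 call ended without control replicates 1 or 2, replicate 3 at 1 µM, replicate 2 at 10 µM or replicates 1 or 3 at 100 µM (0.0528 to 0.114). That of fatty acid synthesis ended without control replicate 2, replicate 1 at 10 µM or replicates 1 or 3 at 100 µM (0.0529 to 0.0888), and that of mitochondrially encoded genes without replicate 1 at 100 µM (0.0584).

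After 6 weeks at 10 nM, 11 of 15 immediate early genes, which respond rapidly to growth factors and stress, had a higher mean than in controls, with a median of 1.20 (camera adjusted p = 0.0132, and adjusted p = 0.582 with an estimated correlation). FOSB was at 1848 ± 111 against 720 ± 172 (log2 fold change 1.38 ± 0.27), and FOS, EGR1 and NR4A2 had fold changes of 2.80 ± 0.68, 2.70 ± 0.65 and 2.41 ± 0.57. RHOB, a small GTPase, was at 1133 ± 116 against 461 ± 58.7, ID2, an inhibitor of helix-loop-helix factors, at 118 ± 9.13 against 32.1 ± 15.6, and HES1 at 2687 ± 358 against 915 ± 317. On the lower side, SAP25, SH3D21, the helicase PIF1 and the tricellular junction gene LSR had fold changes of -2.18 ± 0.54, -1.53 ± 0.39, -1.09 ± 0.29 and -1.83 ± 0.50. Limma called 0 of 12201 genes (smallest adjusted p = 0.0953, 5365 at an unadjusted p under 0.05), edgeR 0 and DESeq2 3706. The first component alone separated the groups, so the 7361 genes without overlap (10% by chance) are not independent evidence. FOSB lies on chromosome 19 from 45467996 to 45475179, RHOB on chromosome 2 from 20447074 to 20449440, and HES1 on chromosome 3 from 194136148 to 194138732, in GRCh38.p14.

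Of the immediate early genes 7 passed at 10 nM adjusted over the list alone, as did 7 with the replicate block and 1 with the first principal component as a covariate, and without control replicate 2 the camera adjusted p of the list was 0.15. Ribosomal proteins were lower in 38 of 38 cases, with a median of -1.23 (adjusted p = 5.56e-10), and 31 passed adjusted over the list alone, against 0 with the replicate block and 0 with that covariate. The respiratory chain had a median of -0.80 (adjusted p = 0.000764) and mitochondrially encoded genes -1.36 (adjusted p = 0.00416), with 0 genes passing adjusted over the list alone. The adjusted p was 0.582 for each of these 3 lists with an estimated correlation. With 2, 3 and 4 components as covariates mitochondrially encoded genes turned to 0.16, 0.20 and 0.19 (adjusted p = 0.0171, 2.88e-05 and 5.84e-07), and with 3 and 4 the respiratory chain to 0.054 and 0.040 (adjusted p = 0.706 and 0.868). The ribosomal share was 8.73% to 12.5% at 10 nM against 16.0% to 17.9% in controls, and the mitochondrial share 5.99% to 7.82% against 9.24% to 11.4%.

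Several other lists had members on both sides at 10 nM. Of 12201 genes 5365 had an unadjusted p under 0.05, so passing adjusted over a list alone need not be specific to it. In cholesterol synthesis and uptake, 7 genes so passed as higher and 4 as lower, and 0 over all genes (list median -0.02, mean 0.01, camera adjusted p = 0.897). HMGCS1 had a fold change of 1.75 ± 0.54, SQLE 1.92 ± 0.67 and EBP -1.57 ± 0.56. Of the endothelial inflammation and NF-kB genes, 14 of 19 were higher (median 0.71, adjusted p = 0.107), and 3 so passed as higher. The cytokines IL6, IL1A and CXCL8 had fold changes of 1.92 ± 0.51, 1.12 ± 0.32 and 1.67 ± 0.46, and the NF-kB subunits NFKB2 and RELB -1.71 ± 0.64 and -1.63 ± 0.55. Adjusted over the list alone, 5 genes passed as higher and 4 as lower for hypoxia and glycolysis (median 0.00, mean -0.08, adjusted p = 0.953), 4 and 2 for mesenchymal transition (median 0.59, adjusted p = 0.471), 1 and 4 for epithelial markers (median -1.37, adjusted p = 0.0949), and 1 and 1 for replication-dependent histones (median -0.26, adjusted p = 0.488). Of these 6 lists 1 gene so passed with the replicate block, in mesenchymal transition as lower, and 1 with the first component as a covariate, there as higher.

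At 100 nM for 6 weeks, RHOB was at 1114 ± 76.6, FOSB at 1652 ± 94.1 and HES1 at 2366 ± 164, with fold changes of 1.28 ± 0.25, 1.22 ± 0.27 and 1.42 ± 0.36. FOS and EGR1 had fold changes of 2.35 ± 0.68 and 2.12 ± 0.65, and MYRIP 1.86 ± 0.52. NPFF, C11orf91 and CHAC1 had fold changes of -1.65 ± 0.50, -0.84 ± 0.25 and -1.95 ± 0.63. The immediate early list had a median of 0.95 (camera adjusted p = 0.00466), with 7 genes passing adjusted over the list alone, 5 with the replicate block and 1 with the first component as a covariate. The median of ribosomal proteins was -0.78 (adjusted p = 3.24e-08), mitochondrially encoded genes -1.01 (adjusted p = 0.00466) and the respiratory chain -0.50 (adjusted p = 0.0138), with 0 genes passing adjusted over the list alone. The adjusted p of these 4 lists was 0.553 with an estimated correlation, and without control replicate 2 the preset one was 0.177 for the immediate early list and the respiratory chain and 0.0564 for mitochondrially encoded genes. With 3 components as covariates mitochondrially encoded genes, the respiratory chain and ribosomal proteins turned to 0.13, 0.072 and 0.019 (adjusted p = 0.046, 0.0359 and 0.996). The ribosomal share at 100 nM was 10.9% to 15.1%. Over all genes limma called 0 (smallest adjusted p = 0.272, 1483 at an unadjusted p under 0.05), edgeR 0 and DESeq2 3. The groups did not overlap for 5774 genes, with the limit given at 10 nM.

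At 1 nM for 6 weeks, PPP1R16B and MPP1 had fold changes of 0.60 ± 0.24 and 0.46 ± 0.22, and neither passed. Ribosomal proteins had a median of -0.24 (camera adjusted p = 9.21e-06), the respiratory chain -0.12 (adjusted p = 0.037), mitochondrially encoded genes -0.29 (adjusted p = 0.0422) and extracellular matrix 0.12 (adjusted p = 0.0422), each with an adjusted p of 0.664 with an estimated correlation. Without replicate 1 at 1 nM these medians were 0.29, 0.12, 0.31 and -0.07. All 4 calls also ended without control replicate 1 (0.454 to 0.751), the last 3 without control replicate 2 (0.206 to 0.509), and those of the respiratory chain and extracellular matrix without replicate 3 at 1 nM (0.221 and 0.334). Immediate early genes were lower in 13 of 15 cases, with a median of -0.15 that did not pass (adjusted p = 0.0748) and passed with the replicate block (0.0366, with an adjusted p of 0.69 with the block and an estimated correlation). Adjusted over the list alone, 1 histone gene passed (0 with the block) and 0 of these 4 lists, and over all genes limma called 0 (31 at an unadjusted p under 0.05), edgeR 0 and DESeq2 2.

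Over the 4 groups at 6 weeks, FOSB, RHOB and HES1 had slopes of 0.54 ± 0.09, 0.48 ± 0.08 and 0.65 ± 0.11 per dose step, with unadjusted p of 4.27e-05, 5.72e-05 and 9.51e-05 and a smallest adjusted p of 0.0979. FOS and EGR1 had slopes of 0.99 ± 0.21 and 0.94 ± 0.21. Of the immediate early genes 8 passed adjusted over the list alone, and the list had a median slope of 0.41 (camera adjusted p = 0.00473, adjusted p = 0.569 with an estimated correlation and 0.0762 without control replicate 2). Ribosomal proteins had a median slope of -0.34 (adjusted p = 2.15e-08, with 19 genes passing adjusted over the list alone), mitochondrially encoded genes -0.39 (adjusted p = 0.00473) and the respiratory chain -0.22 (adjusted p = 0.0069), each with an adjusted p of 0.569 with an estimated correlation, and that of the respiratory chain with the preset one was 0.0762 without control replicate 2. Adjusted over the list alone, genes also passed as higher or lower for inflammation (9 and 2, list adjusted p = 0.0508), cholesterol (9 and 5), hypoxia (5 and 4), epithelial markers (1 and 4), coagulation (2 and 0) and ATF4 genes (2 and 1). With the replicate block these counts were 9 higher for immediate early genes, 5 and 0 for inflammation, 1 and 4 for epithelial markers and 0 for the others, ribosomal proteins included. With the first component as a covariate they were 7 higher for immediate early genes and 0 for the others named. With 2, 3 and 4 components mitochondrially encoded genes turned to a slope of 0.057, 0.055 and 0.055 (adjusted p = 0.00243, 0.00047 and 1.95e-05). Over all genes limma called 0, edgeR 0 and DESeq2 3174, with 5447 genes at an unadjusted p under 0.05. Without replicate 1 at 1 nM limma called 7084 genes for this trend.

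After 12 weeks at 100 nM, SELP, the adhesion receptor P-selectin of activated endothelium, was at 69.9 ± 10.96 against 230 ± 36.7, a log2 fold change of -1.70 ± 0.42. CCM2L, an endothelial paralogue of CCM2, was at 99.1 ± 13.5 against 283 ± 88.3, and CCN5, a matricellular protein, at 59.2 ± 40.4 against 208 ± 98.1. CSF2 and GBP2, an interferon-induced GTPase, had fold changes of -1.15 ± 0.32 and -1.28 ± 0.37. INSC, a polarity adaptor, was at 153 ± 16.6 against 67.7 ± 5.24, and STXBP6, the prostaglandin receptor gene PTGER4, YRDC and ATF3 had fold changes of 0.95 ± 0.30, 1.15 ± 0.39, 0.74 ± 0.26 and 0.94 ± 0.33. None passed, since limma called 0 of 12304 genes (smallest adjusted p = 0.751, 287 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1, and the groups did not overlap for 571 genes, where chance gives 10%. SELP lies on chromosome 1 from 169588849 to 169630124 and INSC on chromosome 11 from 15111416 to 15269676, in GRCh38.p14.

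Endothelial identity genes had a median of -0.37 at this dose, with 16 of 22 lower (camera adjusted p = 0.00446, and adjusted p = 0.151 with an estimated correlation). PLVAP, a component of endothelial fenestrae, SOX18, an endothelial transcription factor, MMRN2 and VWF had fold changes of -1.80 ± 0.60, -1.37 ± 0.57, -0.83 ± 0.34 and -0.79 ± 0.34. DNA replication genes were higher in 20 of 24 cases (median 0.37, adjusted p = 0.00169, and adjusted p = 0.151 with an estimated correlation), among them CDC6 at 0.79 ± 0.30, MCM4 at 0.55 ± 0.23 and UHRF1 at 1.54 ± 0.69. Mitosis genes had a median of 0.30 (adjusted p = 0.0329) and endoplasmic reticulum chaperones 0.27 (adjusted p = 0.0329), both with an adjusted p of 0.695 with an estimated correlation. In the xenobiotic response 6 of 7 genes were higher (median 0.47, adjusted p = 0.0491, and adjusted p = 0.261 with an estimated correlation), with TIPARP at 1.28 ± 0.45 and CYP1A1 at 0.74 ± 0.44. For ribosomal proteins the median was -0.60 (adjusted p = 1.53e-06, and adjusted p = 0.821 with an estimated correlation), and their share was 10.2% to 17.3% against 15.1% to 19.7% in controls. Adjusted over the list alone, 0 genes passed in these lists and 0 over all genes. With 4 components as covariates ribosomal proteins turned to 0.099 (adjusted p = 0.00128) and mitosis to -0.021 (adjusted p = 0.509). The adjusted p of the endothelial identity list was 0.0618 without control replicate 3 and 0.0501 without replicate 2 at 100 nM. The mitosis call ended without those libraries or control replicate 2 (0.0729 to 0.211). Calls also ended for the xenobiotic response without control replicates 1 or 3 or replicates 1 or 2 at 100 nM (0.085 to 0.238) and endoplasmic reticulum chaperones without control replicates 1 or 2 or replicate 1 at 100 nM (0.105 to 0.182).

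At 10 nM for 12 weeks, FOSB was at 4213 ± 585 against 1846 ± 434 and ID2 had a fold change of 1.09 ± 0.38. TES had a fold change of 0.83 ± 0.31, and FAM107A, CDCP1, GLYCTK and IDH2, the mitochondrial isocitrate dehydrogenase, -1.19 ± 0.40, -1.25 ± 0.43, -1.22 ± 0.46 and -1.10 ± 0.41. Immediate early genes had a median of 0.50 (camera adjusted p = 0.0184), with KLF4 at 1.02 ± 0.44 and KLF6 at 1.20 ± 0.50. Heat shock chaperones had a median of 0.39 (adjusted p = 0.0184), epithelial markers -0.74 (adjusted p = 0.0184), endoplasmic reticulum chaperones 0.43 (adjusted p = 0.0225), the respiratory chain -0.53 (adjusted p = 0.000866), ribosomal proteins -0.62 (adjusted p = 5.87e-08) and mitochondrially encoded genes -0.62 (adjusted p = 0.0483). With an estimated correlation the adjusted p was 0.541 for 6 of these lists and 0.583 for mitochondrially encoded genes. With 2, 3 and 4 components as covariates mitochondrially encoded genes turned to 0.19, 0.18 and 0.14 (adjusted p = 0.00149, 0.000367 and 0.000485). The ribosomal share at 10 nM was 11.3% to 20.6%, and without control replicate 1 the adjusted p was 0.25 for the immediate early list and 0.0661 to 0.113 for the other lists but ribosomal proteins. Calls also ended for immediate early genes, heat shock chaperones, epithelial markers and endoplasmic reticulum chaperones without replicate 1 at 10 nM (0.0551 to 0.197). Those of endoplasmic reticulum chaperones, epithelial markers and mitochondrially encoded genes ended without control replicate 2 (0.0562 to 0.367), and the last also without replicates 2 or 3 at 10 nM (0.18 and 0.0886). Adjusted over the list alone 0 genes passed, and over all genes limma called 0 (168 at an unadjusted p under 0.05), edgeR 0 and DESeq2 2.

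At 1 nM for 12 weeks, MYPN and AKIRIN2 had fold changes of 0.74 ± 0.30 and 0.69 ± 0.30, and CCN5 and CXXC5 -1.13 ± 0.49 and -0.60 ± 0.27, all not passing. Ribosomal proteins had a median of -0.34 (camera adjusted p = 0.000309) and mitochondrially encoded genes -0.48 (adjusted p = 0.00583), both with an adjusted p of 0.641 with an estimated correlation. Epithelial markers had a median of -0.42 (adjusted p = 0.00259), endoplasmic reticulum chaperones 0.28 (adjusted p = 0.00259) and DNA replication 0.21 (adjusted p = 0.00583), each with an adjusted p of 0.403 with an estimated correlation. Without control replicate 2 the medians were -0.035 for ribosomal proteins, -0.090 for mitochondrially encoded genes, -0.088 for epithelial markers and 0.089 for endoplasmic reticulum chaperones, with preset adjusted p from 0.496 to 0.711. With 3 and 4 components as covariates ribosomal proteins turned to 0.087 and 0.095 (adjusted p = 0.00334 and 4.63e-05). The DNA replication call ended without control replicates 1 or 3 or replicate 3 at 1 nM (0.0511 to 0.101), that of ribosomal proteins without replicate 1 at 1 nM (0.121), and that of mitochondrially encoded genes without that library or control replicate 1 (0.269 and 0.0511). Over all genes limma called 0 (24 at an unadjusted p under 0.05), edgeR 0 and DESeq2 0, and adjusted over the list alone 0 in these lists. Over the 4 groups at 12 weeks SELP, CCM2L and CCN5 had slopes of -0.46 ± 0.13, -0.40 ± 0.12 and -0.51 ± 0.15, and INSC and PTGER4 0.31 ± 0.09 and 0.43 ± 0.12. The median slope of ribosomal proteins was -0.21 (adjusted p = 1.25e-07, and adjusted p = 0.806 with an estimated correlation), DNA replication 0.10 (adjusted p = 0.0185) and endothelial identity -0.12 (adjusted p = 0.0284), both with an adjusted p of 0.273 with an estimated correlation. The respiratory chain had -0.11 (adjusted p = 0.0363, and adjusted p = 0.848 with an estimated correlation) and endoplasmic reticulum chaperones 0.09 (adjusted p = 0.0463, and adjusted p = 0.806 with an estimated correlation). The call of ribosomal proteins passed without each single library, and with 4 components as covariates their slope turned to 0.021 (adjusted p = 0.0359). The other 4 ended without control replicate 1 (0.0642 to 0.352). For the trend limma called 0 genes (273 at an unadjusted p under 0.05), edgeR 0 and DESeq2 2, and adjusted over the list alone 0 passed in these lists.

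Of the 60 list calls for doses and trends, 39 passed after quantile normalization and 46 after the GC and length correction, while 25 and 21 further lists passed. With an estimated correlation 0 of the further ones did. Quantile normalization ended the calls of mitochondrially encoded genes but for that at 6 weeks and 1 nM (camera adjusted p = 0.139 to 0.856). It ended those of ribosomal proteins at 48 h, at 6 weeks for 100 nM and the trend and at 12 weeks for 1 and 10 nM (0.165 to 0.642). It also ended those of the respiratory chain at 48 h and 10 µM, at 6 weeks for 10 nM, 100 nM and the trend and in the 12-week trend (0.0752 to 0.773), and that of ATF4 genes in the 48-h trend (0.176). With it endoplasmic reticulum and heat shock chaperones, coagulation and extracellular matrix passed as higher at 6 weeks for 10 nM (medians 1.06, 0.96, 0.80 and 0.86), 100 nM and the trend. Lists called as higher and lower at 6 weeks were 1 and 3 for 10 nM, 100 nM and the trend alike, against 6 and 1, 5 and 0, and 5 and 0 with it. At 48 h they were 3 and 2, 4 and 4, and 4 and 4 for 10 µM, 100 µM and the trend, against 0 and 3, 2 and 7, and 1 and 7. At 12 weeks they were 2 and 3 for 1 nM and 3 and 4 for 10 nM, against 4 and 1, and 4 and 2. The GC correction gave 1 and 2 at 48 h and 10 µM. At 6 weeks it gave 0 and 1 for 1 nM (against 1 and 3), 3 and 2 for 10 nM, and 3 and 3 for 100 nM and the trend alike. It gave 6 and 3, 6 and 2, and 7 and 3 (against 2 and 3) at 12 weeks for 1 nM, 10 nM and the trend. With it endothelial inflammation genes passed as higher at 6 weeks for 10 nM, 100 nM and the trend (0.80, 0.52 and 0.25).

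**Figure D1:**
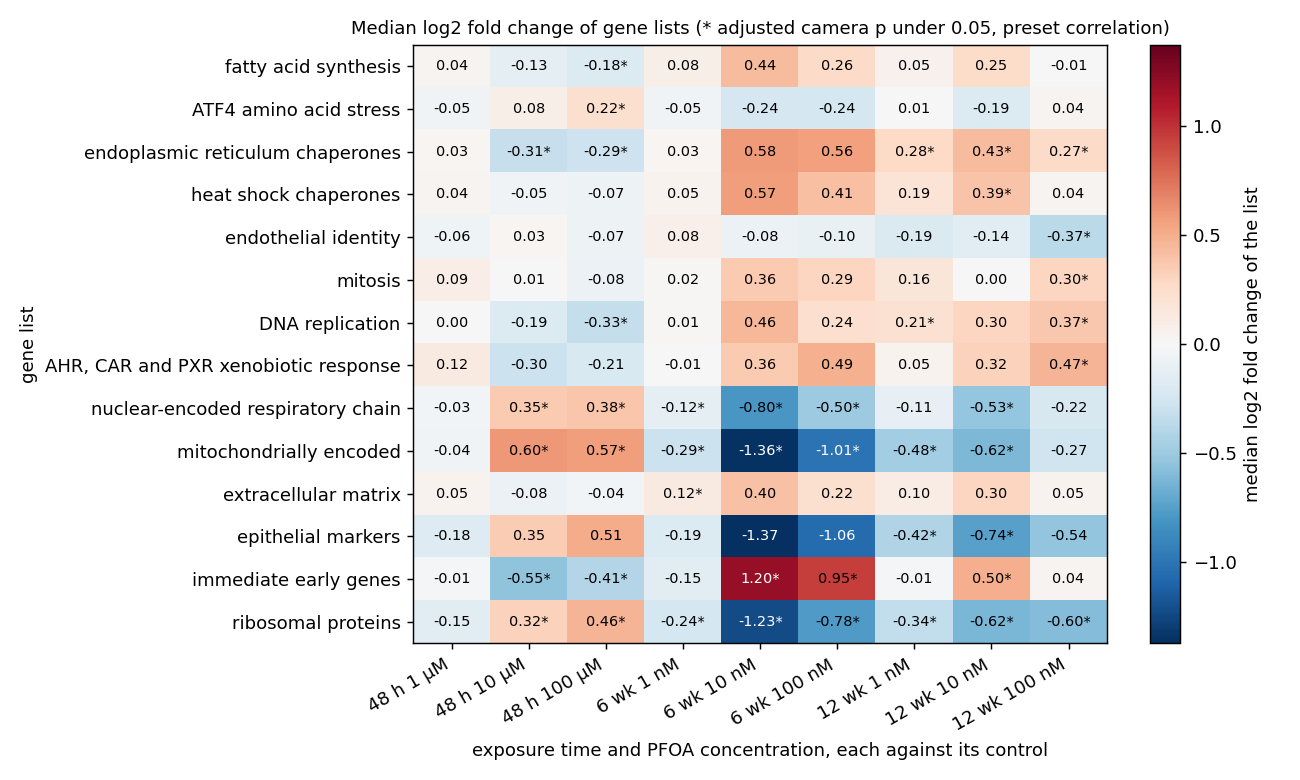
Median log2 fold change of 14 gene lists (vertical axis) by exposure time and PFOA dose against the matching control (horizontal axis), where a star marks a camera adjusted p under 0.05 with the preset correlation. Ribosomal proteins had a median of 0.32 at 48 h and 10 µM, which was -0.08 after quantile normalization, and of -1.23 at 6 weeks and 10 nM.

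Between 12 and 6 weeks, the interferon response differed at 10 nM by camera and not by fry. Its median was -0.13 at 6 weeks and 0.36 at 12 weeks, a difference of 0.50 with 18 of 23 genes higher at 12 weeks (camera adjusted p = 0.000503, adjusted p = 0.0196 with an estimated correlation and fry adjusted p = 0.22). IFI6 had a fold change of -1.13 at 6 weeks and 0.34 at 12 weeks, IFI27 -1.92 and 0.31, and BST2 -1.17 and 0.28. The adjusted p with an estimated correlation was 0.174, 0.0796 and 0.141 without 6-week control replicates 2 and 3 and replicate 1 at 10 nM, and 0.809, 0.0579 and 0.125 without 12-week control replicate 2 and replicates 2 and 3 at 10 nM. Without that 12-week control the preset adjusted p was 0.0935. Adjusted over the list alone 0 genes passed. Of 12037 genes limma called 0 at 1, 10 and 100 nM, with 25, 42 and 68 at an unadjusted p under 0.05, edgeR called 0 at each dose, and DESeq2 2, 1 and 1.

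Fold changes of all genes were also compared between times and doses, across genes, which are not independent replicates. Between 6 and 12 weeks, which have separate controls, r was 0.349 at 1 nM, 0.922 at 10 nM and 0.839 at 100 nM (rho 0.416, 0.928 and 0.867), over 12037 genes with 0 called at either time, so that independent lists would share 0. With the first principal component as a covariate r was -0.0425, 0.325 and -0.0772 at 1, 10 and 100 nM. Without 12-week control replicate 2 it was -0.0772, 0.552 and 0.357 at 1, 10 and 100 nM. At 1 nM it was -0.626 without 6-week replicate 1 at 1 nM, -0.374 without 6-week control replicate 1 and 0.101 without 12-week replicate 1 at 1 nM. At 100 nM it was 0.520 without 12-week replicate 3 at 100 nM. Doses at 1 time share their controls, so part of any excess may come from the shared controls. Unchanged groups simulated against them gave a mean r of 0.428 and covariance of 0.112 at 48 h, 0.281 and 0.0904 at 6 weeks, and 0.410 and 0.152 at 12 weeks. Observed at 48 h, r was 0.0170 between 1 and 10 µM (covariance 0.00148), 0.00289 between 1 and 100 µM (0.000235) and 0.870 between 10 and 100 µM (0.149). At 6 weeks r was 0.566 between 1 and 10 nM (0.149), 0.556 between 1 and 100 nM (0.112) and 0.982 between 10 and 100 nM (0.792). At 12 weeks the same 3 pairs had r of 0.761, 0.805 and 0.811, with covariances of 0.160, 0.154 and 0.261. In that order of pairs 80, 80 and 33 of 100 simulations gave a covariance as large at 48 h, 30, 37 and 0 at 6 weeks, and 36, 37 and 24 at 12 weeks, and simulated r reached 0.966, 0.973 and 0.978 at these times. At 48 h r was 0.208 between 10 and 100 µM without replicate 3 at 10 µM, and 0.554 and 0.551 for the pairs with 1 µM without control replicate 3. At 6 weeks the pairs with 1 nM had -0.707 and -0.705 without replicate 1 at 1 nM, and -0.195 and -0.156 without control replicate 1. At 12 weeks r was 0.366, 0.441 and 0.533 for the 3 pairs without control replicate 2.

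Of the single genes fixed in advance, 22 were tested at each time and none passed at 48 h and 100 µM (SE between 0.24 and 0.78), 6 weeks and 100 nM (between 0.23 and 0.67) or 12 weeks and 100 nM (between 0.26 and 0.70). PDK4, PLIN2, VCAM1 and CYP1B1 lay below the filter. In that order of comparisons, the PPAR target ANGPTL4 had fold changes of 0.98, -1.24 and -0.56, CPT1A, of fatty acid oxidation, -0.02, 0.49 and 0.20, and the metallothionein MT2A 0.22, -0.90 and -0.44. Among cholesterol genes HMGCS1 had -0.08, 1.54 and 0.86, SQLE -0.34, 1.65 and 0.55, and INSIG1 -0.26, 0.88 and 0.26. The stress genes HMOX1, NQO1, DDIT3 and ASNS had -0.77, 0.08, 0.66 and 0.91 at 48 h, 0.46, -0.30, -0.53 and -0.09 at 6 weeks, and 0.60, -0.09, -0.81 and 0.16 at 12 weeks. The endothelial genes NOS3, VWF, PECAM1, CDH5 and ICAM1 had -0.27, 0.18, -0.07, -0.79 and 0.01 at 48 h, -0.47, -0.09, -0.30, 0.61 and -0.13 at 6 weeks, and -0.41, -0.79, -0.55, 0.15 and -0.15 at 12 weeks. CXCL8, PLAT, CDKN1A and MKI67 had 0.20, -0.53, 0.16 and -0.28 at 48 h, 1.16, 0.30, -0.67 and 0.01 at 6 weeks, and 1.62, 0.32, -0.28 and -0.01 at 12 weeks.

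The remaining lists passed in none of the 9 dose comparisons. At 48 h and 100 µM, 6 weeks and 10 nM, and 12 weeks and 100 nM, PPAR targets and fatty acid oxidation had medians of 0.09, 0.08 and -0.12 (camera adjusted p = 0.682, 0.898 and 0.89), and NRF2 oxidative stress 0.07, -0.42 and -0.23 (0.585, 0.439 and 0.762). Coagulation and fibrinolysis had 0.03, 0.50 and 0.05 (0.72, 0.205 and 0.924), the interferon response 0.31, -0.13 and -0.05 (0.428, 0.471 and 0.946), and p53 targets -0.06, 0.50 and 0.04 (0.36, 0.486 and 0.95). Inflammation and NF-kB had -0.19 and 0.26 at 48 h and 12 weeks (0.139 and 0.289), cholesterol synthesis -0.11 and 0.02 (0.428 and 0.89), hypoxia and glycolysis 0.06 and 0.18 (0.958 and 0.852), mesenchymal transition 0.07 and 0.50 (0.958 and 0.682) and histones 0.30 and -0.12 (0.585 and 0.95). Of metallothionein genes, MT1E had fold changes of 0.12, -1.26 and -0.45, MT1X 0.15, -1.02 and -0.45, MT2A 0.22, -1.27 and -0.44, and the zinc exporter SLC30A1 -0.21, 1.33 and 0.44 in the same 3 comparisons, none passing. The leukocyte gene CSF1R had 0.70 ± 0.59, -0.86 ± 0.42 and -0.04 ± 0.43.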

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

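The list tests on differences between 12 and 6 weeks, also without single libraries, the tests of GC content and of exposure on the library score, also at 48 h and 12 weeks alone, the test of exposure on the 6-week genes, the gradient test on immediate early genes, their ratio of mean squares at 6 weeks alone, their splits without the gradient fitted and the splits for genes called were chosen only after the results were seen.

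At 10 nM the shift of the interferon response differed between times by the test of the difference, with a median difference of 0.50 (camera adjusted p = 0.000503, and adjusted p = 0.0196 with an estimated correlation). With the first 1, 2, 3 and 4 principal components as covariates the median difference was 0.31, 0.35, 0.25 and 0.25, and the adjusted p with an estimated correlation lay between 0.000213 and 0.0289. It was 0.00283 after the GC and length correction, 0.0223 with the replicate block and 0.0584 without the 4 libraries with a wide GC gap. Without each of the 12 libraries in turn the median difference was 0.35 to 0.63 and the adjusted p with an estimated correlation 0.00127 to 0.809. It lay above 0.05 without 6 of them, namely 6-week control replicates 2 and 3, 6-week replicate 1 at 10 nM, 12-week control replicate 2 and 12-week replicates 2 and 3 at 10 nM (0.0579 to 0.809). Among these 12 the preset adjusted p lay above 0.05 only without 12-week control replicate 2 (0.0935). Fry gave this difference an adjusted p of 0.22, with 0.413 for 1 component, 0.294 for the block, 0.231 without the 4 libraries with a wide GC gap and 0.213 to 0.973 without single libraries. It passed by fry with 2, 3 and 4 components (0.00211, 0.00117 and 0.00134) and with the GC correction (0.0345).

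Other lists whose shift differed between times at 10 nM were ribosomal proteins by 0.59 (camera adjusted p = 5.78e-07, and adjusted p = 0.632 with an estimated correlation), mitochondrially encoded genes by 0.59 (0.00395, then 0.61), mitosis by -0.37 (0.00598, then 0.452), coagulation and fibrinolysis by -0.38 (0.0289, then 0.193), the nuclear-encoded respiratory chain by 0.36 (0.0289, then 0.632), immediate early genes by -0.33 (0.0289, then 0.522) and replication-dependent histones by 0.56 (0.0301, then 0.193). At 100 nM these were immediate early genes by -0.52 (1.62e-05, then 0.174), mitochondrially encoded genes by 0.59 (3.69e-05, then 0.323), DNA replication by 0.31 (0.00166, then 0.174), endothelial identity by -0.21 (0.00393, then 0.174), ATF4 amino acid stress by 0.30 (0.00835, then 0.207), ribosomal proteins by 0.29 (0.0128, then 0.661), coagulation and fibrinolysis by -0.25 (0.0213, then 0.174) and extracellular matrix by -0.20 (0.0213, then 0.363). At 1 nM they were endoplasmic reticulum chaperones by 0.28 (0.0194, then 0.362), endothelial identity by -0.26 (0.0264, then 0.362), DNA replication by 0.19 (0.0264, then 0.362) and epithelial markers by -0.37 (0.045, then 0.471). Each pair in brackets is the adjusted p with the preset and then the estimated correlation, so none of these 19 held with the estimated one in the fit of all libraries without covariates. In other settings immediate early genes passed with it at 10 nM with 3 and 4 components (adjusted p = 0.00555 and 0.00055) and at 100 nM with 4 (0.0151) and without 12-week replicate 1 at 100 nM (0.0371). Replication-dependent histones passed with it at 10 nM without 12-week control replicate 3 or 6-week control replicate 1 (0.04998 and 0.0182), and DNA replication and endothelial identity at 100 nM without 6-week control replicate 1 (0.0483 each). NRF2 oxidative stress, not among the 19, passed with it at 10 nM without 12-week control replicate 3 (0.04998).

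The libraries of each table lay along a single gradient. GC content and transcript length explained 47.9%, 57.1% and 55.4% of the variance of gene loadings at 48 h, 6 and 12 weeks. The mark was 50% in every table. The score correlated with reads at r = 0.399 (mark 0.7), and at 0.722 without the 2 libraries farthest from the median. Groups held 13.6% of the variance of the library score at 48 h (permutation p = 0.749) and 19.6% at 12 weeks (permutation p = 0.588), with control and treated libraries overlapping at all 3 doses, which argues against exposure as the main source of the gradient at these times. At 6 weeks groups held 51.4% (permutation p = 0.110) and all libraries at 10 and 100 nM lay on one side of the controls, so exposure stays open there. GC content passed its mark only at 6 and 12 weeks. Depth missed its mark over the 36 libraries and was not tested within a time, so both stay open.

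At 6 weeks and 10 nM DESeq2 called 3706 genes, and 2 with the gradient as a covariate. Limma called 0 with that covariate, with 137 genes at an unadjusted p under 0.05. The gradient separates the controls from 10 nM, so the covariate removes a difference between these groups whatever its source. The gradient and an effect of exposure that runs along it therefore cannot be told apart as sources of these calls.

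Immediate early genes had a positive slope over the doses at 6 weeks with the preset correlation (adjusted p = 0.00473) and not with an estimated one (adjusted p = 0.569), with mean list scores of -0.42 in controls, -0.57 at 1 nM, 0.58 at 10 nM and 0.40 at 100 nM. With the gradient as a covariate the median slope was 0.22, which is 53% of the slope without it with a bootstrap spread of 30.3 (adjusted p = 4.53e-22, and adjusted p = 0.0615 with an estimated correlation), and with 2, 3 and 4 components it was 0.17, 0.17 and 0.14 (adjusted p = 0.0182, 0.00371 and 0.0163 with an estimated correlation), so the share that the gradient may account for stays open. Of 100 splits, 2 gave a slope of the list's score as large as 0.361, with a highest other of 0.402, a share under 0.05 for the list taken alone, and 18 gave one as large as 0.134 after the gradient was fitted, with a highest other of 0.272, but the list was picked from 24 after its result was seen and 39 of 100 splits called as many lists in this trend, so chance cannot be excluded for a list chosen in this way. The mean square between groups was 11.9 times that within groups at 6 weeks (exact permutation p = 0.0037 over 15400 splits), which argues against handling of each culture on its own there, with the same limit from the choice of list, although the ratio was 2.53 at 48 h, 1.31 at 12 weeks, and 1.51 at 6 weeks after the gradient was fitted (exact permutation p = 0.302). Handling shared by the cultures of a dose is confounded with exposure, so both stay open, exposure as a hypothesis.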

How the results depend on the processing

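The settings with principal components, with the GC and length correction, with gene-by-gene weights and without the libraries with a wide GC gap, the other settings for agreement, and the left-out libraries for lists, their differences between times and agreement were chosen only after the results were seen. Of the recomputed values of the 15 counts of genes, all 0 with limma, 348 stayed at 0 and 69 rose, and edgeR, the pseudocounts, the filters, the minimum fold, the replicate block and the first component as a covariate gave 0 throughout. Of the 60 list calls, 0 passed with an estimated correlation and 1 with fry, immediate early genes in the 6-week trend, in the fit without covariates. In other settings immediate early genes passed with the estimated one at 6 weeks with 3 and 4 components at 10 nM (adjusted p = 0.00518 and 0.0205) and 100 nM (0.00936 and 0.0338) and with 2, 3 and 4 components for the trend (0.0182, 0.00371 and 0.0163). The interferon response passed at 12 weeks and 10 nM with 2 components (0.0155). ATF4 genes and DNA replication passed at 12 weeks and 100 nM with the GC correction and the block (0.0494 each). In the simulations of the highest doses without the gradient limma recovered 97.0% of 4-fold changes at each time, with 91%, 74.6% and 56.7% of 2-fold and 37.3%, 17.9% and 5.97% of 1.5-fold changes at 48 h, 6 and 12 weeks. Depth and the number of libraries were not varied, so their part in this was not tested. The cause was not tested for any of the changes given here. DESeq2 scaling moved the median of all genes by -0.12 to 0.087 on the log2 scale, edgeR by -0.11 to 0.073, the GC correction by -0.065 to 0.031 and quantile normalization by -0.040 to 0.028.

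Counts of genes passed under DESeq2 were 1 and 1 at 48 h for 1 and 10 µM, 2, 3706 and 3 at 6 weeks for 1, 10 and 100 nM, 3174 for the 6-week trend, 2 and 1 at 12 weeks for 10 and 100 nM, 2 for the 12-week trend, and 2, 1 and 1 for the differences. The GC and length correction gave 2 and quantile normalization 1 for the 6-week trend, and only the 2 groups compared gave 4742 at 6 weeks and 10 nM. The default algorithm for weights stopped before convergence in each of its fits, also with the GC correction, with weights of 1.22e-07 to 559.8 at 48 h, and the gene-by-gene one did not. Library quality weights gave 1645 and 10849 at 48 h for 1 and 100 µM and 7080 for the trend, 9182, 10289 and 8383 at 6 weeks and 10016 for the trend, 4117 and 9087 at 12 weeks for 1 and 10 nM, and 6365 and 4747 for the differences at 1 and 10 nM. Gene-by-gene weights gave 1, 6219 and 6792 at 48 h and 7371 for the trend, 718, 8471 and 5388 at 6 weeks and 8375 for the trend, 1 and 4407 at 12 weeks for 1 and 10 nM, and 171 for the difference at 1 nM. The GC correction with weights gave 1, 8791 and 6583 at 48 h and 7723 for the trend, 5411 and 3271 at 6 weeks for 10 and 100 nM and 6553 for the trend, and 1, 5768 and 995 at 12 weeks and 2987 for the trend. With 2 components as covariates the counts were 2 and 2 at 6 weeks for 10 and 100 nM, 5 for the trend and 1 at 12 weeks and 10 nM. With 3 components they were 5, 8 and 12 in the same order at 6 weeks, 1 and 2 at 12 weeks for 1 and 10 nM, 11 for the 12-week trend and 2 and 2 for the differences at 10 and 100 nM. With 4 components they were 7, 9 and 14 at 6 weeks, 1 and 2 at 12 weeks for 1 and 10 nM, and 2 and 1 for the differences. Leaving out single libraries gave 0 to 1 genes at 6 weeks and 1 nM and 0 to 7084 for the 6-week trend, where the highest values are those without replicate 1 at 1 nM, and 0 elsewhere.

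Replicate numbers did not pair the libraries in all groups. Of 18 pairs of libraries with the same number at each time, 7 at 48 h, 5 at 6 weeks and 8 at 12 weeks had deviations that correlated over 0.1, with ranges of -0.892 to 0.892, -0.861 to 0.808 and -0.846 to 0.874. Not every library correlated best with one of its own number, which held for 6 of 12 at 48 h, 3 of 12 at 6 weeks and 4 of 12 at 12 weeks. With the replicate block limma called 0 genes, and 57 of the 60 list calls passed. Those that did not were ATF4 genes in the 48-h trend (adjusted p = 0.0605), the xenobiotic response at 12 weeks and 100 nM (0.0603) and endoplasmic reticulum chaperones in the 12-week trend (0.0516). Lists passing only with the block were immediate early genes at 6 weeks and 1 nM as lower (0.0366) and inflammation in the 6-week trend as higher (0.0498) and for the difference at 10 nM as lower (0.0497), with no other call changed. Genes passing adjusted over the list alone, summed over the lists, were 74, 7 and 71 at 6 weeks for 10 nM, 100 nM and the trend, against 8, 5 and 19 with the block and 2, 1 and 8 with the first component as a covariate, and other settings gave 10 to 109 at 10 nM and 16 to 90 for the trend. They were 0 to 1 elsewhere and 0 with the block, but with that covariate 20, 26 and 44 at 48 h for 10 µM, 100 µM and the trend and 1, 4, 7 and 2 at 12 weeks, where 3 components gave up to 70. With the GC correction and the block 45 calls stayed and 21 further lists passed. In the correlations of fold changes, the first component as a covariate gave -0.0425, 0.325 and -0.0772 between times at 1, 10 and 100 nM, 0.408, 0.549 and 0.252 between doses at 12 weeks, 0.576 and 0.514 at 48 h for 1 with 10 and 1 with 100 µM, and 0.777 at 6 weeks between 10 and 100 nM. For that last pair the GC correction gave 0.967 and quantile normalization 0.974. Leaving out single libraries gave -0.626 to 0.676, 0.552 to 0.959 and 0.357 to 0.909 between times at 1, 10 and 100 nM, and between doses -0.329 to 0.648, -0.347 to 0.551 and 0.208 to 0.922 at 48 h, -0.707 to 0.899, -0.705 to 0.898 and 0.965 to 0.986 at 6 weeks, and 0.247 to 0.909, 0.365 to 0.921 and 0.472 to 0.909 at 12 weeks. Besides the libraries named beside these values, replicates 2 and 3 at 1 µM at 48 h, replicate 1 at 100 nM at 6 weeks, and replicate 1 at 1 nM and replicate 3 at 100 nM at 12 weeks moved them.

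For these lists the direction of the test turned against that reported, with medians as follows. With the first component as a covariate they were -0.065 for ribosomal proteins at 48 h and 10 µM, -0.0030 (sign kept) for mitochondrially encoded genes in the 6-week trend and 0.071 at 12 weeks and 10 nM, and 0.015 for the respiratory chain in the 12-week trend. With 2 components mitochondrially encoded genes had 0.16, 0.12 and 0.057 at 6 weeks for 10 nM, 100 nM and the trend and 0.19 at 12 weeks and 10 nM, the respiratory chain 0.058 and 0.018 at 6 weeks for 100 nM and the trend and 0.041 at 12 weeks and 10 nM, and ribosomal proteins 0.019 at 12 weeks and 10 nM. With 3 components the respiratory chain had -0.12, -0.082 and -0.031 at 48 h for 10 µM, 100 µM and the trend, 0.066, 0.054, 0.072 and 0.021 at 6 weeks for the 3 doses and the trend, and 0.028 and 0.0030 at 12 weeks for 10 nM and the trend. Ribosomal proteins had -0.13 at 48 h and 10 µM, 0.015 and 0.019 at 6 weeks for 1 and 100 nM, and 0.087 and 0.0065 at 12 weeks for 1 and 10 nM. Mitochondrially encoded genes had -0.055 and -0.017 at 48 h for 100 µM and the trend, 0.20, 0.13 and 0.055 at 6 weeks for 10 nM, 100 nM and the trend and 0.18 at 12 weeks and 10 nM, and mitosis -0.087 at 12 weeks and 100 nM. With 4 components the respiratory chain had -0.10, -0.048 and -0.023 at 48 h, 0.047, 0.040, 0.046 and 0.013 at 6 weeks and 0.040 and -0.0077 (sign kept) at 12 weeks for the same comparisons. Ribosomal proteins had -0.078 at 48 h and 10 µM, 0.015 at 6 weeks and 1 nM, and 0.095, -0.0052 (sign kept), 0.099 and 0.021 at 12 weeks for the 3 doses and the trend. Mitochondrially encoded genes had -0.018 at 48 h and 100 µM, 0.19, 0.12 and 0.055 at 6 weeks and 0.14 at 12 weeks, mitosis -0.021 at 12 weeks and 100 nM, and immediate early genes -0.053 (sign kept) at 48 h and 10 µM. In reverse, medians changed sign and the test did not for ribosomal proteins at 6 weeks and 10 nM and in the trend with 3 and 4 components and at 100 nM with 4 (0.00066 to 0.024). This also held for immediate early genes at 12 weeks and 10 nM with 2 and 3 (-0.017 and -0.033), mitochondrially encoded genes at 48 h for 10 µM with 3 (-0.058) and the trend with 4 (-0.0019), and DNA replication and the xenobiotic response at 12 weeks and 100 nM with 4 (-0.0046 and -0.054), none of which passed. Quantile normalization gave -0.081 for ribosomal proteins at 48 h and 10 µM. Without the 4 libraries with a wide GC gap it was -0.079, and mitochondrially encoded genes had -0.0032 there and 0.019 at 12 weeks and 10 nM. Leaving out single libraries gave -0.16 to 0.89 for ribosomal proteins at 48 h and 10 µM, lowest without replicate 3. At 6 weeks and 1 nM it gave -0.54 to 0.29 for ribosomal proteins, -0.35 to 0.12 for the respiratory chain, -0.69 to 0.31 for mitochondrially encoded genes and -0.073 to 0.23 for extracellular matrix, where all 4 turned without replicate 1.

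Genes fixed in advance turned only with weights, and each value given passed. Library quality weights gave at 6 weeks and 1 nM 0.25 for ANGPTL4, -0.42 for CPT1A, -0.64 for HMGCS1, -0.59 for SQLE, 0.21 for NQO1, -0.13 for PECAM1, -1.08 for CDH5 and -0.41 for ICAM1, then 0.44 for ASNS at 6 weeks and 100 nM, and at 12 weeks and 1 nM -0.54 for SQLE, 0.43 for NOS3 and 0.73 for CDKN1A. With the GC correction and weights CDKN1A had -0.20 at 48 h and 10 µM and 0.57 and 0.51 at 12 weeks for 10 and 100 nM, and NOS3 and MKI67 had 0.35 and -0.35 at 6 weeks and 10 nM. Gene-by-gene weights gave -0.35 for VWF and -0.41 for MKI67 at 48 h and 10 µM and -0.87 for CDH5 at 6 weeks and 1 nM. Over the alternatives the adjusted p ranged from 1.27e-30 to 0.569 for immediate early genes in the 6-week trend, from 1.54e-08 to 0.326 for DNA replication at 48 h and 100 µM, from 7.29e-06 to 0.151 for endothelial identity at 12 weeks and 100 nM, and from 4.96e-10 to 0.214 for ATF4 genes at 48 h and 100 µM.

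Of the 60 list calls, 19 passed in the same direction without any single library, and 41 did not pass or turned without at least 1, given with the camera adjusted p without it, or its range where several are named, each left out on its own. All but those of the 12-week trend stand beside their comparisons. For the 12-week trend these were endoplasmic reticulum chaperones without control replicates 1, 2 and 3, replicate 1 at 1 nM, replicate 1 at 10 nM or replicate 1 at 100 nM (0.0536 to 0.164), endothelial identity without control replicates 1 and 3, replicate 1 at 10 nM or replicates 1 and 2 at 100 nM (0.053 to 0.147), DNA replication without control replicates 1 and 3 (0.0642 to 0.0941), and the respiratory chain without control replicate 1, replicate 3 at 10 nM or replicates 1 and 3 at 100 nM (0.0551 to 0.546). Of the lists that turned, 3, 6 and 8 passed in the other direction with 2, 3 and 4 components (5.84e-07 to 0.046), among them mitochondrially encoded genes at 6 weeks and 100 nM with 4 (0.00691), and ribosomal proteins at 6 weeks and 1 nM without replicate 1 at 1 nM (0.0223). None of those with components passed with an estimated correlation.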

Other observations

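The splits for genes called were chosen only after the results were seen, as were the covariate settings and the GC correction named here.

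Of the genes passing over all genes, CSRNP1 and SERPINB10, a serpin, fall outside the naming rule. They were chosen after their values were seen. Components came from the tested values, and no pass given here with them was checked with splits. At 6 weeks and 10 nM with 2 components FOSB (1.47, limma adjusted p = 0.0445) and CSRNP1 (0.96, adjusted p = 0.0126) passed, and at 100 nM FOSB (1.31, adjusted p = 0.0408) and RHOB (0.96, adjusted p = 0.0408). Without covariates CSRNP1 had 0.38 ± 0.30 at 10 nM. RHOB also passed at 100 nM with DESeq2 (1.25, adjusted p = 0.00371). In the 6-week trend FOSB passed with the GC correction and with quantile normalization (slopes 0.73 and 0.63, limma adjusted p = 0.0194 and 0.0408), and CSRNP1 with the GC correction (0.36, adjusted p = 0.0284). At 12 weeks and 10 nM SERPINB10 passed with 2 components (2.44, limma adjusted p = 0.0296) and had 2.20 ± 0.39 without, and it passed in the 12-week trend with DESeq2 (0.77, adjusted p = 0.0231) and with 3 components (0.70, limma adjusted p = 0.039). IFI6, an interferon-induced gene, passed at 10 nM with 3 components (0.94, limma adjusted p = 0.025) and had 0.34 ± 0.45 without. EGR1 passed for the difference between 12 and 6 weeks at 100 nM with 3 components (-1.28, limma adjusted p = 0.000108) and had -2.23 ± 1.05 without.

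Splits of the libraries were counted for each comparison. For genes called by limma, 10 of 10 splits gave as many as the real 0 in each of the 9 dose comparisons. The highest other count was 0 at 48 h for all 3 doses, 6795, 0 and 0 at 6 weeks for 1, 10 and 100 nM, and 0, 3872 and 1 at 12 weeks. A split cannot give fewer than 0, so these numbers decide nothing. For the trends 100 of 100 splits gave as many as the real 0, with highest others of 2424, 6586 and 6322 at 48 h, 6 and 12 weeks, and for the differences at 1, 10 and 100 nM 100 of 100, with 6131, 7906 and 1. Splits that call many more genes than the real one point to a structure of the libraries. For genes at an unadjusted p under 0.05 the splits with as many were 8, 4 and 2 of 10 at 48 h (real 6, 345 and 244, highest other 117, 5752 and 1481), 9, 1 and 1 at 6 weeks (real 31, 5365 and 1483, highest other 7650, 802 and 313) and 9, 5 and 6 at 12 weeks (real 24, 168 and 287, highest other 2860, 6114 and 2150), where 10 splits cannot give a share under 0.05. For the trends they were 18, 5 and 33 of 100 (real 520, 5447 and 273, highest other 6157, 7608 and 7317), so chance cannot be excluded.

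For lists called, the splits that gave as many were 10, 3 and 1 of 10 at 48 h (real 0, 5 and 8, highest other 6, 5 and 5), 4, 5 and 6 of 10 at 6 weeks (real 4, 4 and 4, highest other 6, 6 and 8) and 2, 1 and 3 of 10 at 12 weeks (real 5, 7 and 6, highest other 5, 6 and 7). With 10 splits the share cannot lie under 0.05. For the trends they were 6, 39 and 27 of 100 (real 8, 4 and 5, highest other 10, 9 and 10), and for the differences 27, 7 and 6 of 100 (real 4, 8 and 8, highest other 8, 9 and 13), so chance cannot be excluded for these.

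With gene-by-gene library weights, 7, 3 and 3 of 10 splits gave as many at 48 h (real 1, 6219 and 6792, highest other 1682, 7299 and 7701), 8, 2 and 5 at 6 weeks (real 718, 8471 and 5388, highest other 9542, 9587 and 7866) and 9, 6 and 10 at 12 weeks (real 1, 4407 and 0, highest other 4690, 9705 and 5215). At 6 weeks and 10 nM 1 of 10 splits gave as many for DESeq2 (real 3706, highest other 0) and 1 of 10 for the 2 groups alone (real 4742, highest other 0), and 10 splits cannot give a share under 0.05. For the 6-week trend with 2 components, 6 of 100 splits gave 5 genes or more, with a highest other of 1884, so chance cannot be excluded.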
